A study of Solanum lycopersicum and Solanum habrochaites with 12 samples.

How the data were processed

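RNA from leaves was measured on 12 Affymetrix tomato arrays, 3 in each of 4 groups. The groups were an early blight susceptible and a resistant genotype, each as uninoculated controls and 24 h after challenge with spores from a 10-day-old culture of the fungus Alternaria solani. Groups and replicate numbers were taken from the sample titles. The labels call the second genotype both resistant and tolerant, and it is called resistant here. They give the susceptible plants as Solanum lycopersicum and the resistant plants as Solanum habrochaites, so each comparison between genotypes is also one between species. Tomato probes may bind transcripts of the second species less well, which was not tested, since no probe or transcript sequences were used here. The labels do not say whether the replicates came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

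The deposited values are on a log scale and were made with MAS5, the Affymetrix probe set summary, per the submitters' processing notes, which give no version. They were read as log2 values, although the authors' log base is not given in the sources used here. Base 10 is excluded by a range of up to 8.51 within a probe set, but a natural log is not, and with it every fold given here would be smaller than the true one. In the deposited table the values of each probe set are centred on their median over the 12 arrays, to within 5e-07. Differences between arrays are therefore kept, while levels, signal over background and differences between probe sets are lost. Any scaling between arrays is not given in the sources used here, and no further normalization was applied.

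The table held 10209 probe sets. The 171 control and reporter probe sets were left out of the tests, which leaves 10038. No filter on dim probe sets was possible on centred values. The platform annotation paired 909 probe sets with 1 gene symbol and none with several, naming 803 genes, of which 786 were found by gene ID in the RefSeq table. The other probe sets are unnamed here. No gene descriptions were given.

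A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom, and 5 contrasts were tested by moderated statistics with a mean-variance trend. Calls are at a Benjamini-Hochberg adjusted p of 0.05 within each contrast. Errors of log2 differences are limma's standard errors (SE). The trend runs over row means, which in centred rows are not brightness. It enlarged the error by over 2 times for 9 probe sets, among them those of PR1b1, CHI3, P4 and ER21, and shrank none by that much. All 4 groups share 1 estimate of spread, although the resistant control arrays varied more than the others. In simulated data with the spread of each group, 344 of 9838 unchanged probe sets were called between the resistant groups, against 6 of 9838 in the simulation of the susceptible comparison. For the susceptible comparison the fit recovered 24% of log2 changes of 0.5, 74% of those of 1 and 90% of those of 2, out of 50 each. For the resistant comparison it recovered 38%, 86% and 96%. In that simulation 19, 43, 48 and 50 changed probe sets were recovered at log2 changes of 0.5, 1, 2 and 4. Together these are fewer than the 344 false calls. Where few probe sets change, the adjusted p therefore understates the false calls between the resistant groups.

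Before the data were examined, 25 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule takes, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those that pass and whose groups do not overlap, 6 each way for the difference of inoculation effects, and up to 4 passing members of each list. It had asked for a gene description and for the brightest probe set of a gene. Neither exists here, so a symbol or synonym stood in for the description, and the plain probe set first in ID order was used. Lists were to be filled partly by descriptions. Instead 157 memberships come from the fixed symbols, 13 from name patterns and 100 from the meaning of symbols, the last assigned after the files were seen but before any gene's value was. The 21 lists with 3 or more genes were tested against the other genes with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over 105 tests. Camera called 0 of 20 unchanged and 20 of 20 shifted simulated lists of 10 genes in the susceptible comparison. The simulated genes varied independently, so this does not show how often lists of genes that vary together are called falsely. None of the calls made on the real data held with an estimated correlation. That estimate was above 0.01 for PR genes (0.092) and photosystem genes (0.39), among others. It was below 0.01 for root markers (-0.14), proteinase inhibitor genes (-0.081), chromatin and cell cycle genes (-0.023), heat shock genes (-0.015) and cell wall genes (-0.0012). A higher correlation was therefore not what ended the calls of these lists, and a lost call is no sign that their genes vary together.

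The alternatives were quantile normalization, median centring, the replicate number as a block, fits of only the compared groups, no trend, a robust fit, array weights, stricter thresholds, 1 probe set per gene, leaving out each array, and other list tests. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision.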

Results

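The 12 arrays cover leaves of a susceptible genotype, given as Solanum lycopersicum, and a resistant one, given as Solanum habrochaites, uninoculated or 24 h after inoculation with A. solani, the fungus that causes early blight, with 3 arrays per group. The design asks how the transcripts of the 2 genotypes differ in response to the fungus. Differences between the genotypes include those between the species and any mismatch of the second species with the tomato probes. The first principal component held 62.7% of the variance and separated the genotypes, and the second held 18%. The median standard deviation (SD) within a group was 0.08 log2 units in susceptible controls and 0.08 in inoculated susceptible plants, 0.27 in resistant controls and 0.12 in inoculated resistant plants. Array controls also differed between groups. The 27 hybridization control probe sets averaged -1.1 ± 0.12 (SD, n = 3) in susceptible controls, -1.35 ± 0.09 in inoculated susceptible plants, 2.27 ± 0.17 in resistant controls and 1.12 ± 0.18 in inoculated resistant plants. The 36 poly-A control probe sets averaged 4.92 ± 0.04 in inoculated resistant plants, against 0.06 ± 0.22 in resistant controls. The 3′ minus 5′ difference averaged over 4 control transcripts (actin, elongation factor 1-alpha, GAPDH and ubiquitin) was -0.12 ± 0.14 in susceptible controls and -0.59 ± 0.03 in inoculated susceptible plants. It was 1.42 ± 0.68 in resistant controls and 0.13 ± 0.09 in inoculated resistant plants, so this mean was lower after inoculation in both genotypes. Phytochrome B2 and the control named GlutTrans, left out of the mean, were instead lower in resistant (-0.91 and -0.18) than in susceptible controls (0.38 and 0.13). In the resistant genotype they were higher after inoculation, at -0.57 and 0.37, as was GAPDH, at 0.31 against 0.20. No batch is labelled, so array processing and group cannot be told apart.

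**Figure D1:**
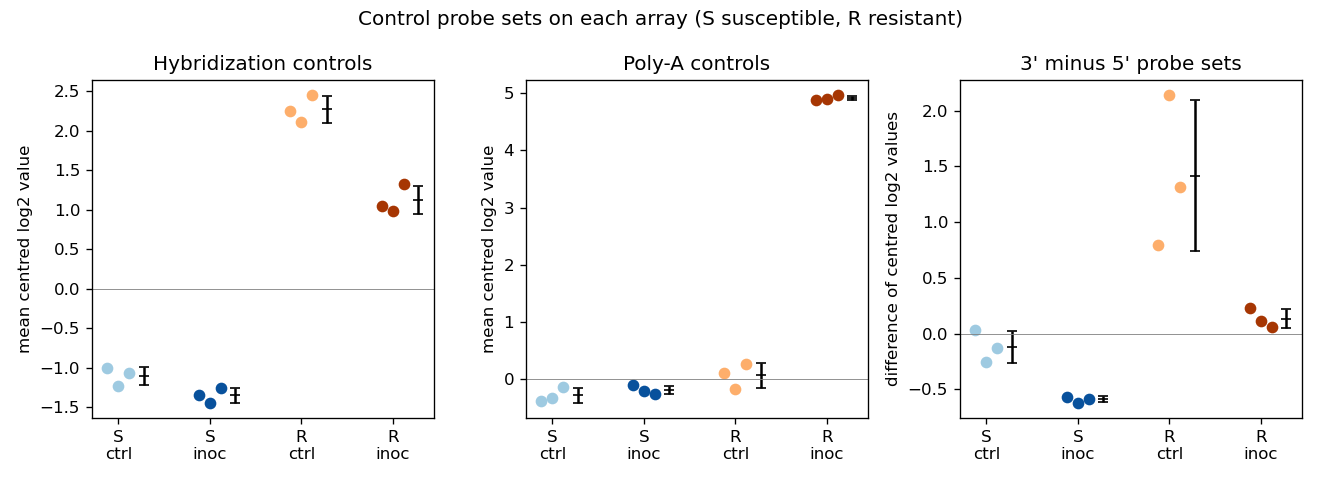
Control probe sets on each array, as mean centred log2 values (left and middle) and as the 3′ minus 5′ difference (right); points are arrays, bars the group mean ± SD (n = 3). The poly-A controls stand at 4.92 in inoculated resistant plants only, and the hybridization controls are above 0 in both resistant groups.

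In the susceptible genotype DES, a divinyl ether synthase gene, rose after inoculation by 6.99 ± 0.21 log2 units (SE, n = 3 arrays per group), which is 127-fold. Genes of pathogenesis-related (PR) proteins followed, with TSI-1 up by 5.67 ± 0.27, P4 by 5.59 ± 0.86, the chitin-binding PR-P2 by 5.45 ± 0.20, the thaumatin-like PR-5 by 4.72 ± 0.27 and the glucanase gene GluB by 4.24 ± 0.16. TD2, a threonine deaminase acting against herbivores, rose by 4.94 ± 0.07 and Wiv-1, a cell wall invertase, by 3.88 ± 0.15. The dehydrin gene TAS14 (-3.26 ± 0.12), the cellulase gene cel5 (-2.37 ± 0.12) and the small heat shock gene HSP17.4 (-2.36 ± 0.14) fell.

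Of 14 PR genes, 12 rose and 2 fell, with a median of 3.59, and the counts were the same adjusted over the list alone. The 2 that fell were CHI17 (-1.04 ± 0.09) and P69A (-0.64 ± 0.19). Camera placed the list above the other genes (Benjamini-Hochberg adjusted p = 1.65e-06, and adjusted p = 0.0769 with an estimated correlation). PR1b1 rose by 6.93 ± 2.30, but its call was lost when any 1 of the inoculated susceptible arrays or resistant control replicate 1 or 2 was left out, and its other probe set gave 0.35. The call of P4 was lost without resistant control replicate 1. Both errors were enlarged by the trend. Without it they were 0.63 for PR1b1 and 0.18 for P4, with adjusted p = 1.78e-05 and 1.93e-08 by limma with Benjamini-Hochberg.

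Of 12 genes of proteinase inhibitors and anti-herbivore proteins, 6 rose, among them ER1 (3.82 ± 0.21), CEVI57 (3.75 ± 0.17) and the cathepsin D inhibitor gene cathDInh (2.85 ± 0.16), and none fell (camera with Benjamini-Hochberg, adjusted p = 6.92e-05, and adjusted p = 0.0769 with an estimated correlation). In the salicylate list 3 of 4 genes rose, NML2 by 1.23 ± 0.16, NML1 by 0.87 ± 0.09 and NPR1, the salicylate co-receptor, by 0.83 ± 0.09 (camera with Benjamini-Hochberg, adjusted p = 0.00922, and adjusted p = 0.145 with an estimated correlation). Of 6 genes listed as root markers 4 rose, AMT1-2 by 1.99 ± 0.07 and LKT1 by 1.43 ± 0.13 (camera with Benjamini-Hochberg, adjusted p = 0.00497, and adjusted p = 0.1 with an estimated correlation). These encode an ammonium transporter and a potassium channel.

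Genes of the chromatin and cell cycle list fell in 10 of 14 cases and rose in none, with 12 falling adjusted over the list alone. Among those that fell were the cyclin genes CycA2 (-1.73 ± 0.14) and CycA1 (-1.21 ± 0.11) and the cyclin-dependent kinase gene CDKB2 (-1.16 ± 0.11) (camera with Benjamini-Hochberg, adjusted p = 0.000578, and adjusted p = 0.0769 with an estimated correlation). Of 46 genes of cell wall modifying enzymes 18 fell and 6 rose, with Cel2 down at -1.74 ± 0.08 and the expansin gene EXP2 at -1.26 ± 0.09 (camera with Benjamini-Hochberg, adjusted p = 0.00521, and adjusted p = 0.0769 with an estimated correlation). Of 9 genes of receptors and resistance proteins 4 rose and 2 fell, with a median of 0.18, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.165). With only the symbols fixed beforehand, a setting chosen after seeing the data, camera called the 4 genes left as higher (Benjamini-Hochberg adjusted p = 0.00255). That setting also called other antioxidant enzymes higher (adjusted p = 0.0396) and abscisate and dehydration genes lower (adjusted p = 0.0302), which the full lists did not. Eix1, a receptor for fungal xylanase, rose by 2.43 ± 0.33, and Asc-1, which gives resistance to toxins of another Alternaria, by 2.28 ± 0.13.

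Over all probe sets, 3437 of 10038 passed limma's test after Benjamini-Hochberg adjustment, 1673 higher and 1764 lower, and 917 of them changed at least 2-fold. The groups did not overlap for 64.7% of probe sets, against 10% by chance. Fitting only the susceptible arrays gave 5901 calls, and array weights gave 5999. The 3′ minus 5′ difference was also lower after inoculation on these arrays, -0.59 against -0.12, and its share in these calls was not tested.

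**Figure D2:**
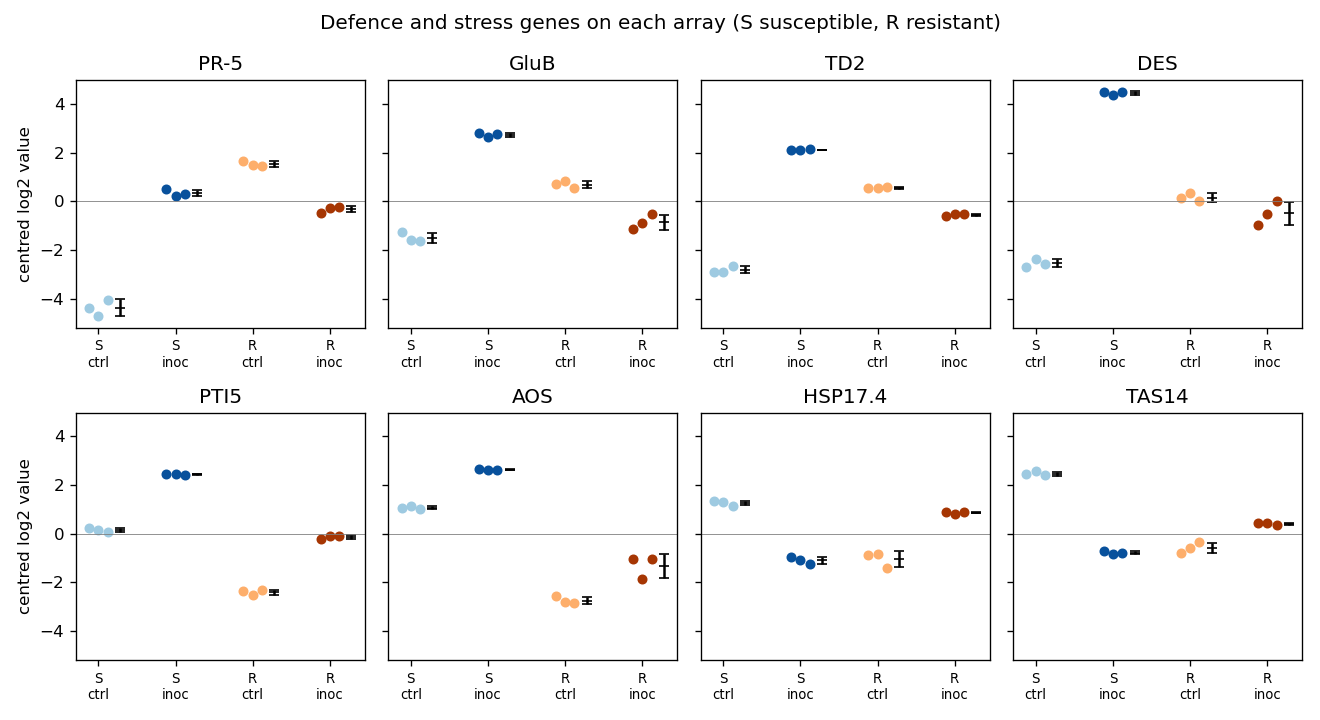
Centred log2 values of 8 genes on each array, with bars for the group mean ± SD (n = 3). GluB, TD2 and DES peak in inoculated susceptible plants, PTI5 and AOS are higher in inoculated than in control plants of both genotypes, and HSP17.4 and TAS14 fell in the susceptible and rose in the resistant genotype.

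In the resistant genotype XET4, a xyloglucan endotransglucosylase gene, rose by 3.55 ± 0.21 (SE, n = 3 arrays per group), the small heat shock genes HSP17-6 and MTSHP by 3.14 ± 0.38 and 2.97 ± 0.27, ER5 by 2.91 ± 0.15, and the chitinase gene CHI17 by 2.85 ± 0.09. ER21 rose by 3.18 ± 0.30, but its other probe set gave -0.85. JA2, placed in the jasmonate list by its name and not by a fixed symbol, and the lipoxygenase gene loxC rose by 2.30 ± 0.31 and 2.28 ± 0.42. The polygalacturonase gene TAPG1 (-3.36 ± 0.33), RSI-1 (-3.30 ± 0.15), the iron reductase gene FRO1 (-3.16 ± 0.11) and GA20OX1, of gibberellin synthesis (-2.38 ± 0.18), fell.

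Of 9 heat shock and chaperone genes 7 rose and 1 fell, with a median of 1.53, HSP21 rising by 2.06 ± 0.20 and HSP17.4 by 1.90 ± 0.14 (camera with Benjamini-Hochberg, adjusted p = 0.0108, and adjusted p = 0.108 with an estimated correlation). Of 10 abscisate and dehydration genes 9 rose, LEA14 by 2.17 ± 0.10, DREB1 by 1.00 ± 0.12 and TAS14 by 0.98 ± 0.12 (camera with Benjamini-Hochberg, adjusted p = 0.00497, and adjusted p = 0.103 with an estimated correlation). Of 14 jasmonate genes 8 rose and 1 fell, loxD rising by 1.63 ± 0.06 and AOS, allene oxide synthase, by 1.42 ± 0.19 (camera with Benjamini-Hochberg, adjusted p = 0.0405, and adjusted p = 0.31 with an estimated correlation). That call was also lost without resistant control replicate 3 (adjusted p = 0.102), with quantile normalization (adjusted p = 0.0934) and with array weights (adjusted p = 0.0714). Chromatin and cell cycle genes fell here too, in 9 of 14 cases with 2 rising and a median of -0.71. Cell wall genes fell in 20 of 46 and rose in 9, with a median of -0.34. Camera with Benjamini-Hochberg called neither list here (adjusted p = 0.111 and 0.275) nor in the difference of inoculation effects (adjusted p = 0.651 and 0.165).

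PR genes fell in 6 and rose in 2 of 14 cases, PR-5 at -1.87 ± 0.27 and GluB at -1.54 ± 0.16, while PR-P2 rose by 1.83 ± 0.20, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.773). Proteinase inhibitor and anti-herbivore genes fell in 7 and rose in 3 of 12 cases, with a median of -0.91, and camera did not call them either (Benjamini-Hochberg adjusted p = 0.282). The 63 probe sets for transgene reporters, which leaf RNA should lack, had a median of -0.49 in this comparison, and the list of flower, pollen and fruit markers one of -0.83. The averaged 3′ minus 5′ difference was lower as well, 0.13 against 1.42, though not for every control transcript, and its share in the calls of this comparison was not tested. In all, 6085 probe sets passed limma's test, 2811 higher and 3274 lower, 2396 of them at least 2-fold. Of these, 905 lay beyond the 95th percentile of the absolute differences of the negative control probe sets, which was 1.57. This count was chosen after seeing the data. Among the changes given above, those of GluB, AOS, DREB1 and TAS14 lay within that bound. Fitting only the resistant arrays gave 4442 calls, and array weights gave 4732. The same settings gave 5901 and 5999 in the susceptible genotype, so which genotype had more calls depended on the model.

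Between the control plants, the resistant genotype had higher values of several PR genes before any inoculation. P4 was higher by 5.98 ± 0.86 (SE, n = 3 arrays per group), PR-5 by 5.92 ± 0.27, and the chitinase gene CHI3 by 3.81 ± 0.72. PR1b1 was higher by 5.80 ± 2.30, a call lost with median centring and without any 1 inoculated susceptible array or resistant control replicate 1 or 2, and that of P4 was lost without resistant control replicate 1. Without the trend both had smaller errors here too, with adjusted p = 1.66e-05 and 2.67e-09 by limma with Benjamini-Hochberg. The ascorbate peroxidase gene APX1 was higher by 3.80 ± 0.15 and CEVI57 by 3.71 ± 0.17. Lower in the resistant genotype were MTSHP (-4.22 ± 0.27), AOS (-3.82 ± 0.19), ER5 (-3.82 ± 0.15), LEA14 (-3.19 ± 0.10), TAS14 (-3.05 ± 0.12) and the ethylene synthesis gene ACS6 (-2.94 ± 0.12).

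Of 14 PR genes 10 were higher and 2 lower, with a median of 2.12, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.179). Proteinase inhibitor and anti-herbivore genes were higher in 7 of 12 cases and lower in 3, with a median of 1.06, also without a call by camera (Benjamini-Hochberg adjusted p = 0.371). On the same arrays all 63 reporter probe sets were higher, with a median of 1.29, as were 16 of 21 flower, pollen and fruit markers, with a median of 1.43. Genes of the photosystems were lower in 7 of 9 cases and higher in none, the photosystem I gene psaD (LOC543978) at -1.25 ± 0.06 and CAB6A at -0.80 ± 0.06 (camera with Benjamini-Hochberg, adjusted p = 0.00733, and adjusted p = 0.311 with an estimated correlation). Abscisate and dehydration genes were lower in 7 of 10 cases and higher in 1 (camera with Benjamini-Hochberg, adjusted p = 0.0138, and adjusted p = 0.145 with an estimated correlation). Jasmonate genes were lower in 8 of 14 and higher in 3, those lower including OPR1 (-2.62 ± 0.09) and loxD (-1.94 ± 0.06), with an adjusted p of 0.0455 from camera with Benjamini-Hochberg, and adjusted p = 0.31 with an estimated correlation. Quantile normalization, median centring, array weights and all probe sets of the listed genes each ended the jasmonate call, with adjusted p = 0.109, 0.0681, 0.0758 and 0.0508 by camera, as did leaving out susceptible control replicate 1, resistant control replicate 2 or 3, or inoculated resistant replicate 1.

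In total 7330 probe sets passed limma's test, 4462 higher and 2868 lower, and the median of all probe sets was 0.22. With quantile normalization the calls split evenly, 3618 higher and 3542 lower. Of the main calls 1121 lay beyond the 95th percentile of the absolute differences of the negative controls, which was 2.00. Among the genes given above for this comparison, psaD, CAB6A and loxD lay within that bound.

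Between inoculated plants, 2 chalcone synthase genes of flavonoid synthesis were higher in the resistant genotype, CHS1 by 4.63 ± 0.18 (SE, n = 3 arrays per group) and CHS2 by 3.23 ± 0.09. XET4 was higher by 3.24 ± 0.21, loxC by 3.09 ± 0.42, the DELLA gene GAI by 3.01 ± 0.10 and EIN2, of ethylene signalling, by 2.62 ± 0.10. Lower were the proteinase inhibitor gene ARPI (-5.04 ± 0.31), DES (-4.94 ± 0.21), the tyramine hydroxycinnamoyl transferase gene THT7-8 (-4.69 ± 0.17), TSI-1 (-3.98 ± 0.27), AOS (-3.96 ± 0.19), cathDInh (-3.79 ± 0.16) and GluB (-3.59 ± 0.16).

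PR genes were lower in 9 of 14 cases and higher in 1, with a median of -1.19 (camera with Benjamini-Hochberg, adjusted p = 0.0132, and adjusted p = 0.26 with an estimated correlation). Proteinase inhibitor and anti-herbivore genes were lower in 7 of 12 and higher in none (camera with Benjamini-Hochberg, adjusted p = 0.00597, and adjusted p = 0.1 with an estimated correlation). Photosystem genes were lower in 7 of 9 (camera with Benjamini-Hochberg, adjusted p = 0.0132, and adjusted p = 0.323 with an estimated correlation). The 5 ribosomal protein genes were all lower, from rpl38 at -0.67 ± 0.08 to RPL3 at -0.16 ± 0.05, and RPS25 at -0.89 ± 0.09, whose other probe set gave 0.31 (camera with Benjamini-Hochberg, adjusted p = 0.0409, and adjusted p = 0.246 with an estimated correlation). Chromatin and cell cycle genes were higher in 11 of 14, the histone gene H1 by 1.63 ± 0.27 and PCNA by 1.55 ± 0.07 (camera with Benjamini-Hochberg, adjusted p = 0.0405, and adjusted p = 0.15 with an estimated correlation). The ribosomal call was lost without any 1 resistant control array or without inoculated resistant replicate 1, and the cell cycle call without inoculated susceptible replicate 2 or resistant control replicate 2, the last leaving 3 of 5 lists. With only the 2 groups compared both calls were lost, with adjusted p = 0.092 for the ribosomal and 0.0595 for the cell cycle list by camera with Benjamini-Hochberg. The ribosomal call was also lost with array weights (adjusted p = 0.0758) and with all probe sets of the listed genes (adjusted p = 0.123). With only the symbols fixed beforehand, the cell cycle list had an adjusted p of 0.207 by camera with Benjamini-Hochberg. The reporters were higher here too, with a median of 0.88. Limma called 6504 probe sets, 3836 higher and 2668 lower, with a median of 0.18 over all probe sets. Quantile normalization gave 3574 higher and 3616 lower, median centring 3201 and 3167, so the excess of higher calls depends on the scaling. Beyond the negative control bound, 1.68 for this comparison, lay 1069 of the calls. H1, PCNA and the 5 ribosomal protein genes lay within it.

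**Figure D3:**
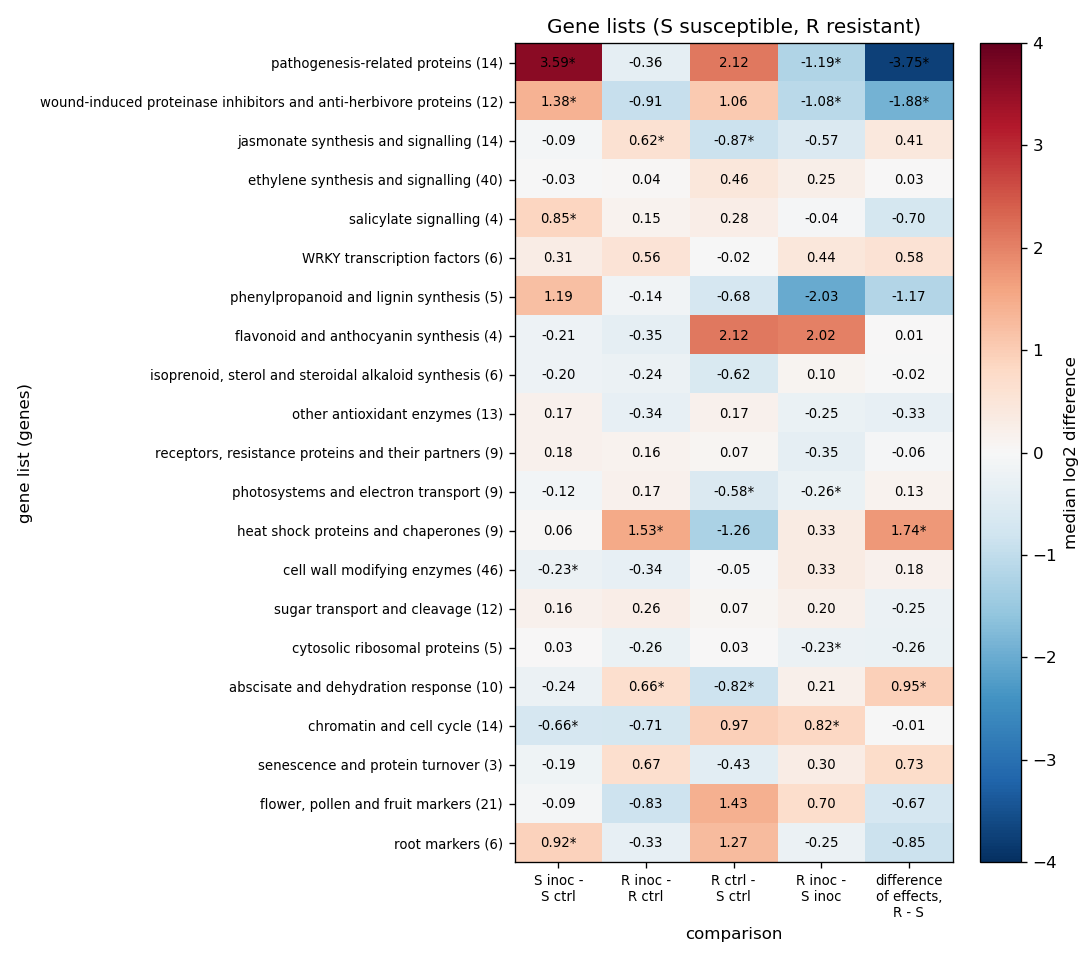
Median log2 difference of each gene list (rows, with the number of genes) in each comparison (columns), with an asterisk where camera's adjusted p passed the threshold. PR genes stand at 3.59 in the susceptible inoculation comparison and at -3.75 in the difference of the inoculation effects.

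The difference of the inoculation effects, resistant minus susceptible, tests where the genotypes responded unequally. Among genes that passed it was most negative for DES (-7.64 ± 0.30, SE, n = 3 arrays per group), P4 (-6.76 ± 1.22), TSI-1 (-6.60 ± 0.39), PR-5 (-6.59 ± 0.38), TD2 (-6.04 ± 0.10) and GluB (-5.78 ± 0.23). It was most positive for HSP17.4 (4.26 ± 0.20), TAS14 (4.24 ± 0.17), XET4 (4.09 ± 0.30), MTSHP (4.01 ± 0.38), ER24 (4.00 ± 0.42) and CHI17 (3.89 ± 0.12). For PR-5 and P4 the susceptible controls were the group that stood apart, at -4.38 ± 0.35 and -5.07 ± 0.31 (SD, n = 3), while the other groups lay between -0.33 and 1.54. The call of P4 was lost without resistant control replicate 1. PR1b1, at -6.93 ± 3.25, did not pass (limma with Benjamini-Hochberg, adjusted p = 0.105), but did without the trend (adjusted p = 0.000146).

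PR genes had the lower effect in the resistant genotype in 11 of 14 cases and the higher in 1 (camera with Benjamini-Hochberg, adjusted p = 0.000797, and adjusted p = 0.145 with an estimated correlation), and proteinase inhibitor and anti-herbivore genes had the lower in 8 of 12 and the higher in 1 (camera with Benjamini-Hochberg, adjusted p = 0.00251, and adjusted p = 0.0769 with an estimated correlation). Heat shock genes had the higher effect in 7 of 9 and the lower in 2 (camera with Benjamini-Hochberg, adjusted p = 0.0339, and adjusted p = 0.15 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0596). Abscisate and dehydration genes had it in 6 of 10 and the lower in 1 (camera with Benjamini-Hochberg, adjusted p = 0.00595, and adjusted p = 0.108 with an estimated correlation). Limma called 4834 probe sets, 2304 higher and 2530 lower, of which 1212 lay beyond the negative controls.

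Some genes changed alike in both genotypes, whose inoculation comparisons share no array. PTI5, an ethylene response factor, rose by 2.29 ± 0.08 (SE, n = 3 arrays per group) in the susceptible and by 2.27 ± 0.08 in the resistant genotype, and AOS by 1.56 ± 0.19 and 1.42 ± 0.19. OPR3, of jasmonate synthesis, rose by 0.81 ± 0.10 and 1.02 ± 0.10, MYC2 by 0.73 ± 0.08 and 0.94 ± 0.08, while CycA1 fell, with -1.21 ± 0.11 and -1.53 ± 0.11. All these susceptible values lay beyond the negative control bound of 0.37 for that comparison. Of the resistant values only that of PTI5 lay beyond the bound of 1.57. In all, 2433 probe sets passed limma's test in both genotypes, 813 higher in both and 798 lower in both, where independent lists would share 468.5 and 575. The other 822 changed in opposite directions. A 2-fold minimum left 276 shared in direction, and the negative control bound, chosen after seeing the data, left 268. Hybridization controls were also lower after inoculation in both genotypes, by differences of -0.25 and -1.15, so a technical shift could give shared signs. Across probe sets, which are not independent replicates, the log2 differences correlated with Pearson's r of 0.19 and Spearman's rho of 0.22.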

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

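The test of 5′ ends, the comparisons of PR genes with tissue markers and the test for exchanged labels were chosen after the values were seen, and the bounds for PR genes on the inoculated arrays were rewritten after their value was known, which moved weak signal from excluded to open. The test on reporters was set down before the reporters were looked at, but after other array controls had been.

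The inoculation effects of the genotypes differed by the interaction test for 4834 probe sets. The same test gave median differences of -3.75 for PR genes, -1.88 for proteinase inhibitor and anti-herbivore genes, 1.74 for heat shock genes and 0.95 for abscisate and dehydration genes. Among genes it gave 4.26 for HSP17.4, 4.24 for TAS14, 4.09 for XET4, 4.01 for MTSHP, 4.00 for ER24, 3.89 for CHI17, -7.64 for DES, -6.76 for P4, -6.60 for TSI-1, -6.59 for PR-5, -6.04 for TD2 and -5.78 for GluB. Control probe sets outside the comparisons carried signal of their own. Poly-A controls averaged 4.92 in inoculated resistant plants, hybridization controls 2.27 in resistant controls, and reporters lay 1.29 higher in resistant than in susceptible controls.

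The resistant control arrays stand apart, with 7330 probe sets differing from the susceptible controls. One candidate explanation is weak target signal that was scaled up. It was to give a reporter median of at least 0.5, and the median was 1.29. Another is loss of 5′ ends in the RNA. In the averaged 3′ minus 5′ difference the lowest resistant control array exceeded the highest susceptible one by 0.762. Phytochrome B2 and GlutTrans, left out of that mean, were lower in resistant controls, which goes against such a loss for these transcripts. Neither explanation excludes a difference between the genotypes, which the labels give as different species. Loss of signal where tomato probes mismatch the second species was not tested and is not excluded either. Array processing follows the groups, so the share of each stays open.

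PR genes had the lower inoculation effect in the resistant genotype in 11 of 14 cases (camera with Benjamini-Hochberg, adjusted p = 0.000797, and adjusted p = 0.145 with an estimated correlation), but 9 of 100 splits of the arrays, the real one among them, called as many lists in this comparison. Such splits can keep the inoculation effect of 1 genotype, so this share does not measure chance alone. On the inoculated arrays PR genes minus tissue markers gave -1.96 (permutation test, two-sided, p = 4e-05 over 14 and 21 genes, which are not independent), which speaks against scaled-up weak signal as the cause of the low values if it raised both alike, but it stays open, since it would compress strongly expressed genes, and photosystem and ribosomal protein genes were lower there too, though with medians of -0.26 and -0.23 less so than PR genes with -1.19. As the cause of the high values in resistant controls, scaled-up weak signal stays open as well, since PR genes exceeded the markers there by 1.12 (permutation test, two-sided, p = 0.0696). Of 14 PR genes, 4, P4 and PR-5 among them, lay above the highest marker at 3.25. They are the highest of the list, so they do not decide the question. Exchanged labels of the resistant control and inoculated arrays also stay open, as does probe mismatch in the second species, which was not tested. Of 917 probe sets changed at least 2-fold in the susceptible genotype, 64.6% had the same sign in the resistant one, which speaks against an exchange, but the bounds for this test were set after a similar share was known, and hybridization controls were lower on inoculated than on control arrays in both genotypes, with differences of -0.25 and -1.15, so a technical shift could give shared signs.

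Other divisions of the arrays were fitted to ask whether chance could give as many calls. For the 2-group comparisons 3 against 3 arrays make 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many probe sets, and the highest of the others gave 0 against 3437 in the susceptible genotype, 3 against 6085 in the resistant one, 0 against 7330 between controls and 0 against 6504 between inoculated plants. For the lists 1 of 10 splits likewise gave as many, with 5 at the highest against 6, 2 against 3, 2 against 3, and 2 against 5. For the difference of effects 1 of 100 splits, the real one, gave as many probe sets, 3085 being the highest other. These splits exchange control and inoculated arrays within each genotype. They can also leave the labels of 1 genotype as they are or swap them whole, which keeps its inoculation effect. The 3085 calls may therefore hold inoculation effects and do not measure what chance gives. The splits ask whether inoculation had no effect at all, not whether its effects were equal. Splits that mix the groups also widen the spread, so chance is not excluded for the difference itself. For changes shared by both genotypes 1 of 100 gave as many, 1 being the highest other against 1611, but other splits call almost no probe sets to share, whereas independent responses would share 468.5 higher and 575 lower, so this decides nothing. For the 4 lists called in the difference of effects, 9 of 100 splits, the real one among them, called as many, and the highest of the others called 6. Since splits can keep the inoculation effect of 1 genotype, this share does not decide the question, and chance is not excluded for the lists.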

How the results depend on the processing

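The counts beyond the negative controls, the lists of fixed symbols and the genotype difference shared by control and inoculated plants (4393 probe sets) were chosen after seeing the data. Offsets and floors on linear values and filters on dim probe sets were not run, since the values are centred logs, and signal over background is unknown. Where a count moved by over 1.5 times, the cause was not tested, except that stricter thresholds pass fewer probe sets. In the order of the report's 5 comparisons, a 2-fold minimum left 917, 2396, 3739, 2813 and 2324 probe sets, with 276 shared by both genotypes' responses and 1639 genotype differences shared. An adjusted p of 0.01 left 1002 shared responses. The negative control bound left 905, 1121, 1069 and 1212 in the last 4 comparisons, 268 shared responses and 452 shared genotype differences. The susceptible count rose to 5901 with only the 2 groups and 5999 with array weights. An estimated correlation called 0 lists in every comparison, and fry, which does not compare a list with other genes, called 19, 19, 17, 20 and 19. Between inoculated plants, 3 lists were called with only the 2 groups. Leaving out each array gave 2662 to 4063, 5503 to 6367, 6756 to 7490, 5825 to 7183 and 4189 to 5374 probe sets, 1254 to 1896 shared responses, 3938 to 4836 shared genotype differences, and 6 to 7, 2 to 3, 2 to 3, 3 to 5 and 4 to 5 lists.

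Array numbers did not pair the arrays in general, since deviations of same-numbered arrays correlated over 0.1 in 2 of 18 pairs. Both were pairs of a susceptible control and an inoculated susceptible array, with r of 0.21 and 0.38. The third such pair had 0.04, so pairing within the susceptible genotype stays possible. With the replicate number as a block, 3210, 5956, 7244, 6376 and 4672 probe sets, 1493 shared responses, 4299 shared genotype differences and 6, 3, 3, 5 and 4 lists were called.

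Of 8608 alternative values of 433 named results, 8433 kept direction and call, 163 kept only direction and 12 reversed, all 12 in another probe set of the gene, and the cause was not tested. In the susceptible response this was FESOD (-0.25). In the resistant response they were ER21 (-0.85), Psy1 (0.51), FESOD (2.33) and H1 (0.24). Between controls they were ER21 (1.45), LOC543856 (-0.017) and H1 (-0.12), and between inoculated plants FESOD (2.51) and RPS25 (0.31). In the difference of effects they were FESOD (2.57) and Psy1 (0.77). Median centring moved the median by -0.16 between controls and -0.13 between inoculated plants.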

Other observations

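The cell wall invertase gene Wiv-1 rose by 3.88 ± 0.15 (SE, n = 3 arrays per group) in the susceptible and by 1.71 ± 0.15 in the resistant genotype, with a difference of -2.17 ± 0.21, and the hexose transporter gene HT2 by 2.99 ± 0.24 and 1.17 ± 0.24, with a difference of -1.82 ± 0.34 that also passed. The sucrose synthase gene sus3 went the other way, with 1.03 ± 0.07 and 1.93 ± 0.07. The tyramine hydroxycinnamoyl transferase gene THT1-3 rose by 3.51 ± 0.48 and 2.16 ± 0.48, and its difference did not pass. Camera called neither the sugar list nor the phenylpropanoid list in any comparison. The rise of HT2 in the resistant genotype lay within the negative control bound of 1.57.

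Some lists had too few genes to test. Of 2 peroxidase genes CEVI-1 rose by 3.66 ± 0.09 in the susceptible and fell, with -0.86 ± 0.09, in the resistant genotype. Of 2 glutathione transferase genes GST-T4 rose by 3.01 ± 0.20 and 1.81 ± 0.20. The trichome sesquiterpene synthase gene SSTLE1 fell, with -1.2 ± 0.19, in the susceptible and rose by 1.86 ± 0.19 in the resistant genotype. It also belongs to the list of 6 isoprenoid genes, which camera did not call in any comparison. Of 2 carbonic anhydrase genes, ca1 (LOC543802) changed by -0.46 ± 0.08 in the resistant genotype. That value and the fall of CEVI-1 in the resistant genotype lay within the negative control bound of 1.57. The genotype difference ran the same way in control and inoculated plants for 4393 of the 5148 probe sets called in both, which is 85.3%, where independent lists would share 1705 higher and 762 lower. The 2 comparisons share no array, but all 63 reporter probe sets were higher in both, and 452 of the shared differences lay beyond the negative controls.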
